A study of Mus musculus with 2 samples.

How the data were processed

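Total RNA of mouse brain at postnatal day 10 (strain C57BL/6J) was measured in 2 samples, GPHR F/F;Nes and a GPHR F/F littermate control, 1 array each. Per the labels' protocols, RNA was extracted with TRIzol and labelled with Cy3 by the Agilent low-input method for 1-colour arrays. Per the submitters' processing notes, Agilent Feature Extraction 11.5.1.1 read the scans. The deposited scanner output gives for each spot an intensity on a linear scale, and per the file headers the processed intensity had its background subtracted and spatial trends removed, with a small positive stand-in value for spots not above background. The deposited raw spot and background intensities were used for 1 alternative only, and the deposited flags (other values, 0 or 1 per spot) mark spots that are well above background, saturated or outliers. The deposited table of values for the whole series is on the log2 scale. Set against the scanner output, its 2 columns equalled the log2 processed signal plus 1 constant per array, within 0.001, for 99.9% of the probes on each array, and their medians were -3.19 for the control and -2.92 for GPHR F/F;Nes. The constants, -8.01 and -7.43, lie near minus each array's log2 75th percentile, and the values are not centred per probe. How the authors set them is not given in the sources used here. Probe coordinates are on mm9, per the file headers. Both arrays were on 1 slide and in 1 scan, so neither separates the groups.

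Each array held 62976 spots, of which 59305 were not controls, with 56605 distinct probes and up to 10 spots per probe. Spots with an outlier flag on either array were left out (51 non-control spots flagged on each), which left 56603 probes. Spots of 1 probe were averaged on the log2 scale, and each array's 75th percentile over the probes was subtracted. A probe counted as measured when the software called it well above background on both arrays (36717 probes). A gene's value was the mean over its measured probes, its error the combined error that the scanner software gives for those probes. Genes measured on 1 array alone got a bound, the brighter value against the higher of the dim probe's own signal and the lowest signal well above background on the dimmer array (6.28 units in the control and 5.06 units in GPHR F/F;Nes).

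Probe accessions were matched without versions to a RefSeq gene table of the GRCm38.p6 assembly, used for names only: 32993 of the 56603 probes matched, 1889 received a symbol other than the array's, and all others kept the array's name. The array coordinates place 56022 probes on mm9. No genome sequence was used here, so exons, introns and untranslated regions under the probes were not analysed here.

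With 1 array per group there are no residual degrees of freedom, so no test between groups was made and no p-values are given. Differences of at least 2-fold were counted. Each gene list's median difference was given as a percentile among 10000 random lists of the same size, drawn from 20 bins of mean signal, and lists with fewer than 5 measured genes got values only. In the closing section a list is called apart from random lists when its percentile is at most 2.5 or at least 97.5. Before the data were examined, 39 gene lists and the rule for naming genes were fixed. The rule took Gpr89, the 12 largest differences in each direction among genes with a symbol, at or above the median level and with all probes in 1 direction, the 3 highest bounds in each direction, up to 4 members of each list with the largest differences, lead genes of the lists, and sex-linked and erythrocyte genes as sample checks. The values of some genes that the rule takes are not reported here. Lists share members, Cxcl10, Neurod1, Klf4 and C1qc for example, so their counts are not independent. A further 12 lists were chosen after the values were seen and appear in the closing section alone.

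Alternatives fixed before the data were examined were centring on the median, quantile normalization, a loess correction of the difference on the mean level (span 0.3), normexp background correction (offset 50) with quantile normalization, the deposited value table, no filter or a stricter filter on dim probes, the brightest probe or the median over probes, outlier spots kept, thresholds of 1.5-fold and 3-fold, and random lists not matched on level. Those added after seeing the data were leaving out probes with a GA repeat, using probes designed to curated RefSeq mRNAs alone, scaling to spike-in RNAs, and leaving out probes on chromosomes X and Y. Analyses ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1 for the loess, quantile and normexp steps. The calculation was tested on simulated arrays of 23946 genes for GPHR F/F;Nes against GPHR F/F, with 200 genes changed by known folds. The only noise was that of replicate spots (pooled SD 0.052 and 0.057). All 133 genes changed 2.5-fold or 4-fold passed the 2-fold threshold, and 0 of 67 genes changed 1.5-fold and 0 of 23716 unchanged genes did. Of 200 unshifted lists, 7 (3.5%) fell outside the 2.5 to 97.5 percentiles. The simulation left out the spread between probes of 1 gene, the trend with signal level and genes that move together. It therefore checks the calculation and does not give the rate of false calls on the real arrays.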

Results

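Brain RNA of postnatal day 10 mice of the C57BL/6J strain was profiled on 1-colour Agilent whole-genome expression arrays. The series, titled for the loss of GPHR in the brain, held 2 samples: 1 with the genotype GPHR F/F;Nes and 1 GPHR F/F littermate control (n = 1 per group). GPHR, the Golgi pH regulator, is an anion channel of the Golgi membrane, and in the mouse it is encoded by Gpr89. Each array held 62976 spots, and both were on 1 slide and read in 1 scan. The 75th percentile of the probe signals was 259.5 units in the control and 173.4 units in GPHR F/F;Nes, and 67.0% and 69.2% of the distinct probes were well above background. No spot was saturated on either array.

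All differences below are GPHR F/F;Nes minus GPHR F/F on the log2 scale, each array first set to its own 75th percentile, so "higher" and "lower" are relative to that percentile. Because each genotype had 1 array, no difference has a replicate check and no test between genotypes was made. The ± values are the scanner software's error of the difference, a technical error that leaves out differences between animals and disagreement between probes of 1 gene. This error was nearly constant, at 0.20, for bright genes measured by 1 probe with 1 spot, so it hardly reflects a spread measured gene by gene. For gene lists fixed before the data were examined, the median difference of the measured members was placed among 10000 random lists of the same size and signal level, as a description of these 2 arrays.

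The first question was whether the targeted gene itself differed. Gpr89 was lower in GPHR F/F;Nes by a log2 difference of -0.53 ± 0.22, a 1.44-fold lower normalized signal. The raw signal was 43.3 units in the control and 20.04 units in GPHR F/F;Nes, dim on both arrays but well above background. Among the 2581 probes within 0.25 log2 units of its level, the median difference was 0.20 with an SD of 0.65, and 7.71% of them were lower than Gpr89. Set against that median, Gpr89 was 1.65-fold lower. Its difference was -0.28 after normexp background correction, -0.80 with each array centred on its median and -1.56 after scaling to spike-in RNAs. The array had 1 Gpr89 probe (60 bases, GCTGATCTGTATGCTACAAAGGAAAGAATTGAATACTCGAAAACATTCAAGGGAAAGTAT), placed on the minus strand of chromosome 3 from 96684051 to 96684564 of mm9, a span of 514 bp, so its match is split on the genome. The labels do not name the deleted exons, and a probe outside them checks nothing about the deletion.

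The comparison of the genotypes covered 23946 genes with signal well above background on both arrays. Sterol synthesis genes and neuronal genes were lower in GPHR F/F;Nes, whereas genes of the interferon response, complement, microglia, blood vessels, meninges and choroid plexus were higher. In all, 1901 genes were at least 2-fold higher and 328 at least 2-fold lower, and 21717 differed by less. Several probes measured 228 of the higher genes and 74 of the lower ones, against 8138 of all 23946 genes. A gene symbol was held by 928 of the higher genes and 249 of the lower ones, against 15228 of all. The higher genes thus rested more often on 1 probe and on array entries without a symbol. A further 703 genes had signal well above background in GPHR F/F;Nes alone and 121 in the control alone, each with a bound of at least 2-fold. The median difference over all genes was 0.07 and its SD 0.57. It depended on signal level, with bin medians of 0.41 for the dimmest of 20 bins of genes, 0.45 for the next, -0.12 for bin 18 and 0.05 for the brightest. The split between higher and lower genes depended on the scaling: 85.3% of the 2-fold genes were higher in the main setting, 68.6% after quantile normalization, 57.1% with each array centred on its median and 1.25% after scaling to spike-in RNAs.

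**Figure D1:**
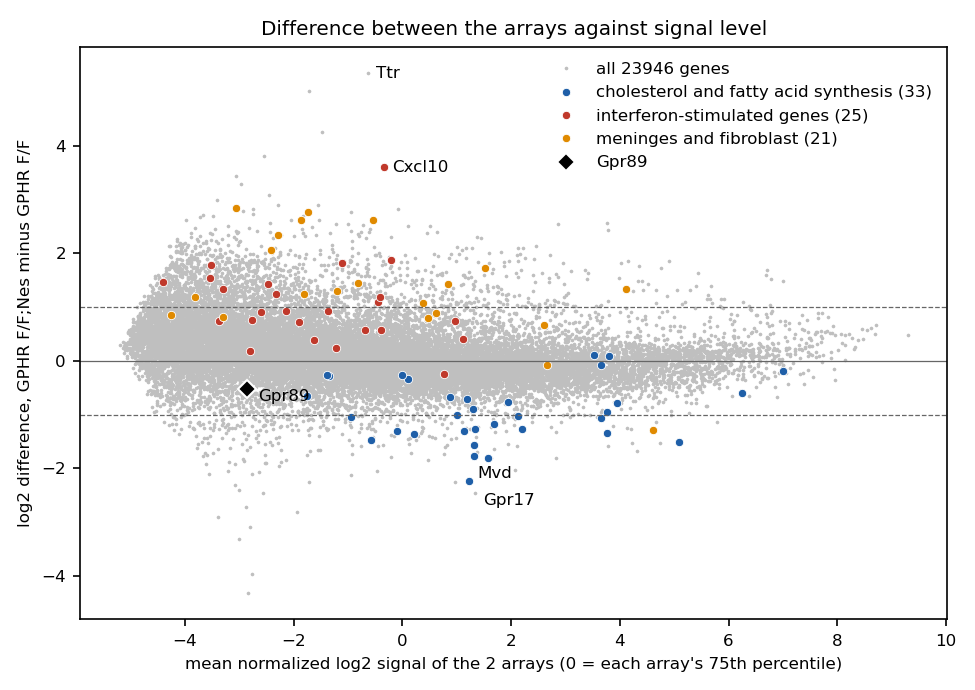
Log2 difference between GPHR F/F;Nes and GPHR F/F (vertical axis) against the mean normalized log2 signal of both arrays (horizontal axis, 0 at each array's 75th percentile) for 23946 genes (grey points). Coloured points are members of 3 gene lists and the diamond is Gpr89 at -0.53. Dashed lines mark a 2-fold difference, and 17 of the 33 cholesterol and fatty acid synthesis genes lie on or under the lower one.

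Genes with a symbol were ranked when their mean level was at or above the median of such genes and all their probes went in 1 direction. Dimmer genes, such as Ttr (5.35) and Penk (-2.05), were left out of this ranking and are given below. Within the ranking, the largest positive difference was that of Cxcl10, a chemokine induced by interferons, at 3.60 ± 0.21 (12.1-fold higher in GPHR F/F;Nes). It was followed by Tssk5 (2.55), Rcn3, an endoplasmic reticulum protein that binds calcium (2.51, SD between its 2 probes 0.10), Olfr1500 (2.40), Tmem52b (2.38) and Rhox3a (2.30). Ecrg4 (2.15), the galectin Lgals1 (2.10), Glycam1 (2.07), the ephrin Efna2 (2.03), the protease inhibitor A2m (2.003) and the small heat shock protein Hspb8 (1.99) completed the 12 largest. The largest negative difference was that of Gpr17, a receptor of oligodendrocyte precursors committed to differentiate, at -2.46 ± 0.20 (5.49-fold lower). The secreted neuropeptide precursor Vgf (-2.26), the mevalonate pathway enzyme Mvd (-2.24), the cationic amino acid transporter Slc7a3 (-2.02), Tafa1 (-1.84), the thyroid hormone-binding protein Crym (-1.82) and Itpka (-1.81) came next. Tm7sf2 (-1.80) and Stard4 (-1.77) of sterol metabolism, Stac (-1.72), the serotonin receptor Htr2c (-1.70) and the neurofilament subunit Nefm (-1.60) completed the 12. Only Rcn3 and Glycam1 of the higher genes, and Vgf, Tafa1, Tm7sf2 and Nefm of the lower, had several measured probes. All others had 1 measured probe, so the rule on direction tested nothing for them.

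Sex-linked genes differed between the 2 arrays together with the genotype. Xist, the RNA expressed from the inactive X chromosome of females, was well above background in GPHR F/F;Nes alone, at least 55.8-fold higher there. The Y-linked genes Eif2s3y, Ddx3y and Uty were well above background in the control alone, where they were at least 38.4-fold, 10.9-fold and 10.6-fold higher. Kdm5d had probes with signal in the control alone and 1 probe with signal on both arrays, at a difference of 0.39 ± 0.20. Tsix had signal in the control alone, at least 1.13-fold higher. The other highest bounds in GPHR F/F;Nes were those of the stress-induced hormone Fgf21, at least 39.1-fold, and the receptor gene Trhr2, at least 14.0-fold. Every comparison of the genotypes was therefore also one between an array with Xist signal and an array with Y-linked signal.

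Genes of cholesterol and fatty acid synthesis were lower in GPHR F/F;Nes as a group. Of 33 measured members, 17 were at least 2-fold lower, none was 2-fold higher and 31 lay below 0. The list median was -1.01 (2.01-fold lower), below every one of the 10000 random lists, whose 95% range was -0.19 to 0.08. Mvd had the largest difference (-2.24 ± 0.20), followed by the sterol reductase Tm7sf2 (-1.80 ± 0.14), the sterol carrier Stard4 (-1.77 ± 0.20) and Dhcr7, which makes cholesterol in its last step (-1.57 ± 0.20).

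**Figure D2:**
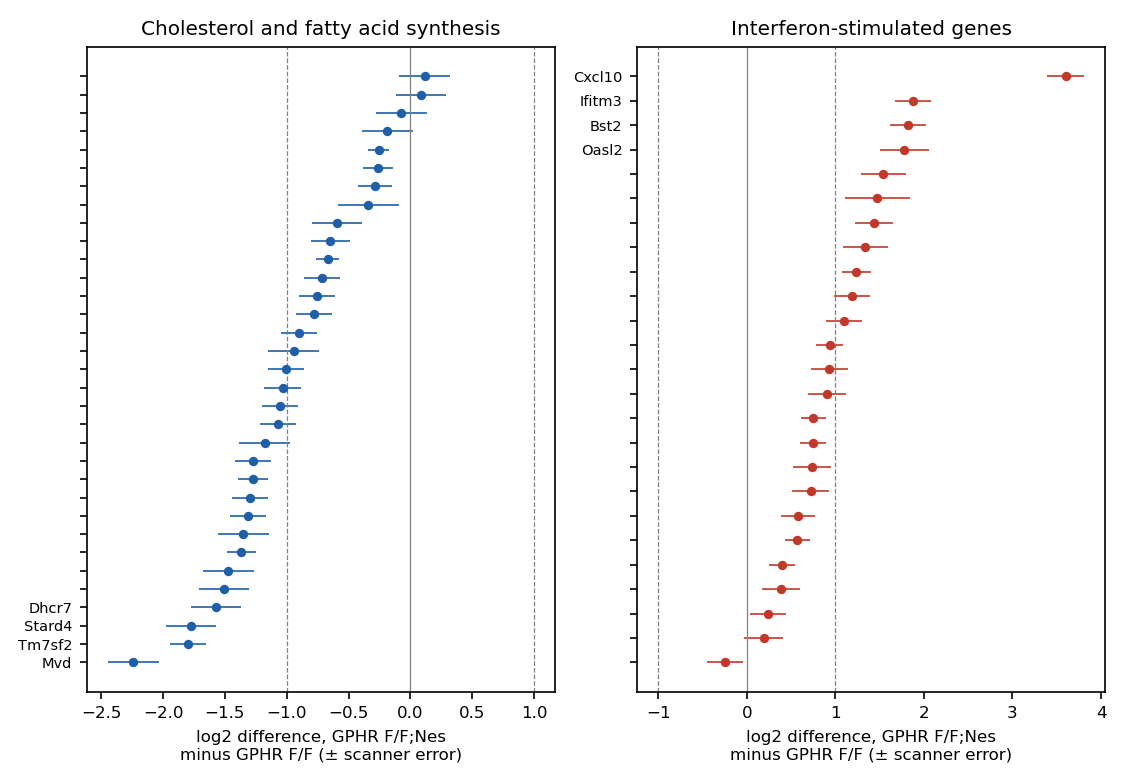
Log2 difference between GPHR F/F;Nes and GPHR F/F (horizontal axis) for each measured gene of the cholesterol and fatty acid synthesis list (left, 33 genes) and of the interferon-stimulated list (right, 25 genes). Points are gene values (the 4 largest differences of each list are named), bars the scanner software's error, and dashed lines a 2-fold difference. Values run from -2.24 for Mvd on the left to 3.60 for Cxcl10 on the right.

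Interferon-stimulated and inflammatory genes were higher in GPHR F/F;Nes. Of 25 interferon-stimulated genes measured on both arrays, 11 were at least 2-fold higher, none was 2-fold lower and 24 lay above 0, with a median of 0.93. A further 5 had signal in GPHR F/F;Nes alone. Besides Cxcl10, Ifitm3 (1.88 ± 0.20), Bst2 (1.82 ± 0.21) and Oasl2 (1.78 ± 0.27), 3 antiviral effectors, had the largest differences. Of 18 genes of chemokines, inflammation and complement, 8 were at least 2-fold higher, none was 2-fold lower and 14 lay above 0, with a median of 0.98. They included the monocyte chemokine Ccl2 (2.32 ± 0.21) and the complement genes C1ra (2.15 ± 0.24), Serping1 (1.89 ± 0.22) and C1qc (1.85 ± 0.23). Both medians lay above every one of the 10000 random lists. After normexp background correction, whose offset shrinks differences of dim probes, they were 0.39 and 0.26, both still at or above the 99.98 percentile. In the same comparison, meninges and fibroblast genes had a median of 1.31 and choroid plexus genes one of 0.94.

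Microglial genes and reactive astrocyte genes were higher too, whereas the general astrocyte list was not set apart in the main setting. Of 22 microglia genes, 9 were at least 2-fold higher and none 2-fold lower (19 above 0 and 3 below, median 0.87), with Trem2 at 2.14 ± 0.23, Tyrobp at 2.08 ± 0.24 and Cx3cr1 at 1.69 ± 0.22. Aif1 differed by 0.41 ± 0.21. Of 22 genes of activated or phagocytic microglia, 8 were 2-fold higher (median 0.73), led by Tlr2 (2.46 ± 0.29), Clec7a (1.57 ± 0.37), Cd52 (1.43 ± 0.22) and Csf1 (1.35 ± 0.12). Of 30 reactive astrocyte genes, 26 lay above 0 and 4 below, and none was 2-fold lower (median 1.13). At least 2-fold higher were 18, among them Cxcl10, the iron-binding lipocalin Lcn2 (2.33 ± 0.21), Gbp2 (1.92 ± 0.21) and Clcf1 (1.88 ± 0.33). All 3 medians lay above every one of the 10000 random lists, though with a stricter filter on dim probes the microglia median was 0.23, at the 94.5 percentile. After normexp correction the medians were 0.24 for microglia, 0.26 for activated microglia and 0.31 for reactive astrocytes, all at or above the 99.99 percentile. The general astrocyte list (25 genes) had a median of 0.09, at the 89.3 percentile of random lists (98.8 to 99.8 in 3 alternative settings), with 2 genes 2-fold higher, Chrdl1 (1.34 ± 0.12) and Ntsr2 (1.16 ± 0.20). Hepacam differed by 0.93 ± 0.21, Clu by 0.93 ± 0.20 and Gfap, the astrocyte intermediate filament, by 0.82 ± 0.14.

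Genes of blood vessels and of the tissues that border the brain were higher in GPHR F/F;Nes, and so were genes of cell division. Of 21 endothelial and pericyte genes, 10 were at least 2-fold higher and none 2-fold lower (15 above 0 and 6 below, median 0.91). The largest differences were those of Vtn (2.89 ± 0.23), Anpep (2.15 ± 0.33) and the contractile genes Tagln (1.83 ± 0.20) and Myl9 (1.54 ± 0.20). A further 2 had signal in the control alone and 1 in GPHR F/F;Nes alone. Of 20 choroid plexus and ependyma genes, 9 were 2-fold higher (median 0.94). Ttr, the transport protein that choroid plexus secretes, had the largest difference of the list (5.35 ± 0.22, 40.9-fold higher), ahead of F5 (1.66 ± 0.36), Rarres2 (1.60 ± 0.20) and Folr1 (1.43 ± 0.15). Of 21 meninges and fibroblast genes, 14 were 2-fold higher and 1 lower (median 1.31). Slc6a13 (2.84 ± 0.28), Igf2 (2.78, probes at 2.32 and 3.23) and the collagens Col3a1 (2.62 ± 0.21) and Col1a2 (2.61 ± 0.21) led that list. Of 33 genes of progenitors and cell division, 3 were 2-fold higher and 1 lower, but 31 lay above 0 (median 0.62). Cdk1 (1.25 ± 0.21), Prom1 (1.103, probes at 0.79 and 1.42) and Aurkb (1.07 ± 0.18) were higher and the Notch target Hes5 was lower (-1.24 ± 0.16). All 4 medians lay above every one of the 10000 random lists, though with a stricter filter on dim probes the endothelial and pericyte median was 0.16, at the 97.2 percentile. After normexp correction it was 0.14 (99.6 percentile), against 0.48 for choroid plexus, 0.82 for meninges and 0.41 for progenitors.

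Neuronal genes were lower in GPHR F/F;Nes by smaller amounts. Of 32 pan-neuronal and synaptic genes, 29 lay below 0 and 3 were at least 2-fold lower, with a median of -0.31. The 3 were the neurofilament subunits Nefm (-1.60 ± 0.14), Nefl (-1.14 ± 0.14) and Nefh (-1.12 ± 0.15), and the neuronal nuclear marker Rbfox3 stood at -0.88 ± 0.12. GABAergic genes had a median of -0.45 over 22 genes, with 2 genes 2-fold lower, the neuropeptide genes Penk (-2.05 ± 0.17) and Tac1 (-1.39 ± 0.15), and 2 genes 2-fold higher, Pvalb (1.37 ± 0.21) and Lhx6 (1.32 ± 0.20). Both medians lay below every one of the 10000 random lists. Glutamatergic genes had a median of -0.29 over 21 genes, at the 0.27 percentile, with Neurod1 (-1.39 ± 0.20) and Nrgn (-1.05 ± 0.20) 2-fold lower, Slc17a7 at -0.89 ± 0.20 and Grin2a at -0.86 ± 0.12. The cerebellar list had a median of -0.13 over 21 genes, at the 3.43 percentile (0.02 to 1.34 in 8 alternative settings), with Neurod1, Car8 (-1.21 ± 0.17) and Pcp4 (-1.14 ± 0.20) 2-fold lower and Slc1a6 at -0.85 ± 0.20.

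Oligodendrocyte lineage genes differed in both directions. Of 19 precursor genes, 16 lay below 0 (median -0.26, 0.37 percentile), with Gpr17 at -2.46, C1ql1 at 1.36 ± 0.22, Sox10 at -0.88 ± 0.20 and Bmp4 at 0.87 ± 0.15. The oligodendrocyte and myelin list (28 genes) had a median of 0.11, at the 62.9 percentile. There, 3 genes were 2-fold higher, Apod (2.78 ± 0.12) and Cryab (1.63 ± 0.20) among them, and 2 were 2-fold lower, Fa2h (-1.30 ± 0.25) and Gpr37 (-1.28 ± 0.21). A further 1 gene had signal in GPHR F/F;Nes alone with a bound of at least 2-fold. The 3 probes of Mbp, a structural protein of myelin, disagreed, at -0.86 for the brightest and 0.53 and 0.47 for the others.

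**Figure D3:**
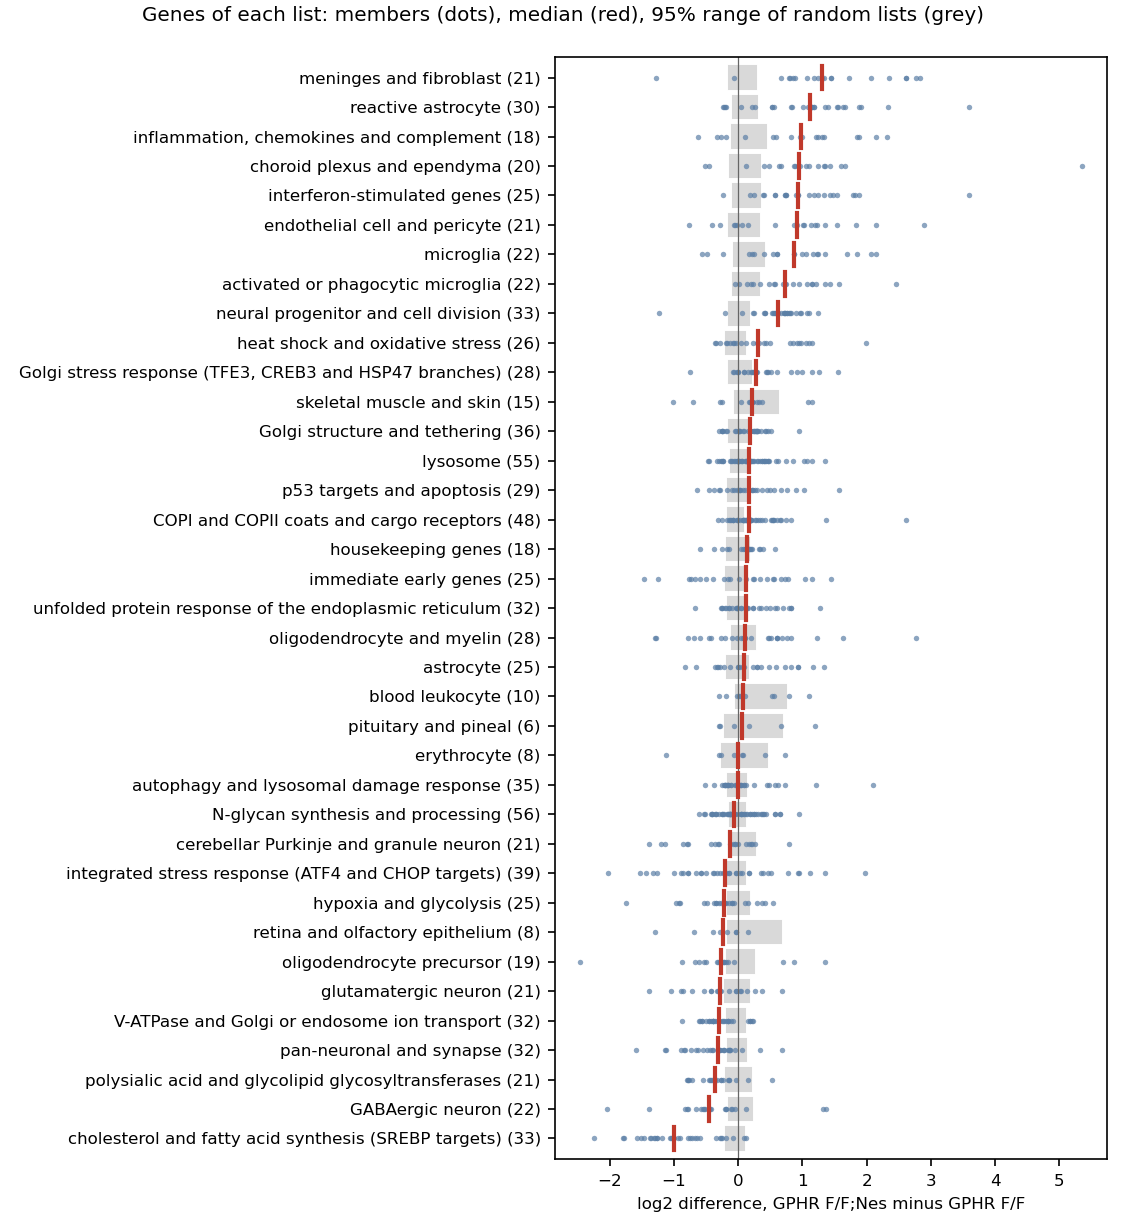
Log2 difference between GPHR F/F;Nes and GPHR F/F (horizontal axis) for the measured members of the 37 gene lists with at least 5 measured genes, lists ordered by median (number of genes in parentheses). Dots are genes, red bars list medians, and grey boxes the 95% range of the medians of 10000 random lists matched on signal level. Medians run from -1.01 for cholesterol and fatty acid synthesis to 1.31 for meninges and fibroblast.

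Genes of the compartment where GPHR acts differed little. Of 36 genes of Golgi structure and tethering, none differed 2-fold, although 27 lay above 0 and the median of 0.19 was at the 99.4 percentile of matched random lists. Golim4 had the largest difference (0.94 ± 0.15), followed by Gorasp2 (0.51, with an SD of 0.67 between its 4 probes), Gosr1 (0.46 ± 0.21) and Tgoln2 (0.43 ± 0.21). The coat and cargo receptor list (48 genes, median 0.17, 99.95 percentile) held 2 genes 2-fold higher, Kdelr3, which returns proteins to the endoplasmic reticulum (2.62 ± 0.21), and Copz2 (1.38 ± 0.12), ahead of Arf4 (0.82 ± 0.20) and Sec24d (0.75 ± 0.20). The Golgi stress list (28 genes, median 0.27, 99.5 percentile) held 3 genes 2-fold higher, the collagen chaperone Serpinh1 (1.56 ± 0.20), Fut1 (1.26 ± 0.27) and Klf4 (1.15 ± 0.20), and Muc1 stood at 0.99 ± 0.35. Lysosome genes (55 genes, median 0.17, 99.8 percentile) included 4 that were 2-fold higher, Ctss (1.35 ± 0.23), Idua (1.15 ± 0.20), Ctso (1.07 ± 0.22) and Aga (1.03 ± 0.20), whereas Ctsd stood at 0.34 ± 0.20 and Lamp1 at 0.18 ± 0.14. These 4 medians lay below 0 when each array was centred on its median, which moved the median of all genes by -0.28, to -0.20. Their percentiles stood at 88.7 to 96.3 against random lists not matched on level. In the same comparison, meninges and fibroblast genes had a median of 1.31, microglia genes one of 0.87 and activated microglia genes one of 0.73.

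Genes of the proton pump and of polysialic acid and glycolipid synthesis were on the lower side, whereas N-glycan genes were not set apart from random lists matched on level. The list of the V-ATPase and of Golgi and endosome ion transport had no 2-fold gene, yet 27 of 32 lay below 0 and the median of -0.30 was at the 0.01 percentile. Clcn6 (-0.88 ± 0.12), Atp6ap2 (-0.61 ± 0.20), Atp6v0c (-0.59 ± 0.14) and Tmem199 (-0.57 ± 0.20) had its largest differences. Of 21 genes for polysialic acid and glycolipid synthesis, 19 lay below 0 (median -0.36, below every one of the 10000 random lists), with St8sia3 at -0.80 ± 0.20, St6galnac5 at -0.78 ± 0.20, Gal3st1 at -0.78 ± 0.23 and St8sia5 at -0.77 ± 0.20. In the same comparison, pan-neuronal genes had a median of -0.31, GABAergic genes one of -0.45 and glutamatergic genes one of -0.29. N-glycan genes (56 genes) had a median of -0.06, at the 21.2 percentile (2.45 against random lists not matched on level), with Man1c1 at 0.94 ± 0.14, St3gal6 at 0.65 ± 0.13, Stt3a at 0.65 ± 0.11 and Fut8 at -0.62 ± 0.15. The autophagy list (35 genes) had a median of -0.01, at the 62.1 percentile, with Lgals1 and Lgals3 (1.21 ± 0.11) 2-fold higher, Calcoco1 at 0.73 (probes at 0.26 and 1.20) and Atg16l1 at 0.62 (probes from -0.13 to 1.01).

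Stress responses went in different directions. The unfolded protein response list (32 genes) had a median of 0.12 at the 95.2 percentile, with Derl3 2-fold higher (1.27 ± 0.22), Pdia4 at 0.82 ± 0.20, Dnajc3 at 0.82 ± 0.20, Atf6 at 0.80 (probes at 0.03 and 1.56) and the chaperone Hspa5 at 0.57 ± 0.12. The integrated stress response list (39 genes, median -0.21, 0.38 percentile) held 3 genes 2-fold higher and 5 lower. Gdf15 was higher (1.97 ± 0.21) and Fgf21 had signal in GPHR F/F;Nes alone, while Slc7a3 (-2.02 ± 0.20), Ddit4 (-1.53 ± 0.20) and Mthfd2 (-1.44 ± 0.14) were lower. Atf4 stood at -0.86 ± 0.14, and the 2 Ddit3 probes disagreed, at 0.01 and 1.53. Heat shock and oxidative stress genes (26 genes, median 0.31, above every one of the 10000 random lists, but a median of 0.035 with each array centred on its median) held 4 that were 2-fold higher, Hspb8, Hspb1 (1.16 ± 0.20), Bag3 (1.101 ± 0.20) and Hmox1 (1.06 ± 0.20). Of these 26 genes, 17 lay above 0 and 9 below, and the 95% bootstrap interval over genes was -0.04 to 0.81. The p53 and apoptosis list (29 genes, median 0.17, 98.2 percentile) held Casp12 (1.57 ± 0.22) and Fas (1.03, probes at 0.46 and 1.60) at 2-fold or more, Gadd45a at 0.90 ± 0.21 and Trp53 at 0.76 ± 0.21, and its percentile lay between 95.3 and 96.9 after quantile normalization, a loess correction, with no filter or with a stricter filter. Immediate early genes (25 genes, median 0.12, 96.4 percentile, 98.6 to 99.8 in 4 alternative settings) held 3 that were 2-fold higher, Ccn1 (1.44 ± 0.20) and Klf4 among them, and 2 lower, Egr3 (-1.47 ± 0.14) and Egr4 (-1.25 ± 0.20). Hypoxia and glycolysis genes (25 genes, median -0.22, 0.47 percentile) held 1 that was 2-fold lower, Hk2 (-1.75 ± 0.23), with Slc2a3 at -0.97 ± 0.16, Bnip3 at -0.92 ± 0.20 and Ankrd37 at -0.90 ± 0.21.

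Lists for blood and for other tissues gave small differences. Erythrocyte genes (8 genes) had a median of -0.01 at the 34.7 percentile, with Hbb-bh1 at 0.73 ± 0.32, Car1 at 0.42 ± 0.22 and Bpgm at -0.29 ± 0.20. Slc4a1 and Klf1 had signal in GPHR F/F;Nes alone, at least 1.96-fold and 1.74-fold higher. Leukocyte genes (10 genes) had a median of 0.07 at the 8.11 percentile, with 1 gene 2-fold higher, Cd79a (1.099 ± 0.39). Pituitary and pineal genes (6 genes) had a median of 0.05 at the 24.6 percentile. Retina and olfactory epithelium genes (8 genes) had a median of -0.23 at the 1.04 percentile (3.12 against random lists not matched on level), with Gng13 at -1.30 ± 0.20. Skeletal muscle and skin genes (15 genes) had a median of 0.21 at the 40.3 percentile, with Tnnt3 at 1.15 ± 0.18, Acta1 at 1.09 ± 0.21 and Krt14 at -1.01 ± 0.31. Housekeeping genes (18 genes) had a median of 0.13 at the 92.6 percentile and none differed 2-fold, with Hprt at -0.60 ± 0.20, B2m at 0.58 ± 0.19, Polr2a at 0.38 ± 0.14 and Gapdh at -0.37 ± 0.08.

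With each array centred on its median, the medians of the p53, unfolded protein response, immediate early, astrocyte, myelin and housekeeping lists lay below 0 as well. In that setting the median of all genes was itself -0.20, and the medians of these lists lay above it.

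Technical spread between replicate spots, and in the median between probes of 1 gene, was small beside the differences of 2-fold or more. Single probes could still be off by more. Of 147 probes with a GA repeat, 89 were 2-fold higher, while other probes of the same genes had a median of -0.026. Over 298 probes with replicate spots well above background, the difference between single spots had an SD of 0.08 (pooled), and over 8138 genes with several probes the SD between probes of 1 gene was 0.20 in the median and 0.36 pooled. Neither covers differences between animals, litters or dissections, and the number of arrays limits the precision. When the arrays were scaled to their spike-in RNAs, every difference moved by -1.03. The medians of the higher lists other than reactive astrocytes and meninges then lay below 0. Their direction therefore holds relative to the other genes of the array and not as an absolute amount. The shift rests on a mean over 8 spike-in probes, with 1 dim probe at 1.30 and the others from 0.15 to 0.41. Medians that ended close under 0 may depend on that 1 probe.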

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

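Of the tests below, the one on other probes of genes measured by GA-repeat probes was set before its result was seen, and all others were chosen only after the results were seen.

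The spike-in RNAs, which the main setting does not use, were brighter on the GPHR F/F;Nes array before any scaling. Their mean log2 difference was 0.45 (SD 0.36 over 8 usable probes, all 8 brighter). Of these, 1 dim probe lay at 1.30 and the others from 0.15 to 0.41. The 75th percentile of the GPHR F/F;Nes array was 1.497-fold lower than that of the control.

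The lower signal of cholesterol and fatty acid synthesis genes in GPHR F/F;Nes (median -1.01) was set against 3 explanations. A trend of the difference with brightness is argued against as the whole cause, since the median after a loess correction was -0.94. The median of the myelin list lay 1.11 above that of the cholesterol list (95% bootstrap interval over genes 0.74 to 1.61). The intervals were 0.69 to 1.49 after loess, 0.58 to 1.12 after normexp correction and 0.48 to 1.90 with a stricter filter. The last reaches under the bound chosen for this gap. For the myelin list as a set, the gap argues against a smaller share of myelin-forming cells as the whole cause. That list held genes in both directions, Apod (2.78) and Fa2h (-1.30) for example. Precursor genes were lower (median -0.26, with Gpr17 at -2.46), so a smaller share of cells at earlier steps of the lineage stays open. The sex of the animals stays open: 0 genotypes had arrays of both sexes by their sex-linked signal, so sex and genotype cannot be told apart for these genes. A lower output of sterol synthesis with the loss of GPHR may be a hypothesis for arrays with replicates of 1 sex.

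The higher signal of microglial, vascular and border-tissue genes in GPHR F/F;Nes was set against 3 explanations. Blood left in the tissue is argued against by the adult alpha haemoglobin genes, with a mean of -0.17 (-0.22 to -0.13, scanner error). A lower share of neuronal RNA as the whole cause would raise all non-neuronal genes alike. Pooled microglia, endothelial and meningeal genes lay 1.03 above pooled astrocyte, oligodendrocyte and precursor genes (95% bootstrap interval 0.77 to 1.32). The intervals were 0.63 to 1.20 after loess, 0.19 to 0.74 after normexp correction and 0.25 to 1.38 with a stricter filter. The pooled genes were thus not raised alike, which argues against a lower share of neuronal RNA alone as the whole cause. The last 2 intervals, however, reach under a bound of 0.3 used at first. A lower share of neuronal, astrocyte and oligodendrocyte RNA together cannot be judged by this contrast, since astrocyte and oligodendrocyte genes are its reference. This contrast does not isolate neuronal share. It holds meningeal genes (median 1.31), which stay open to dissection, and precursor genes that were lower (median -0.26). For the microglial genes alone a lower neuronal share stays open. Microglia minus astrocyte genes, the contrast used at first, gave 0.78 (0.18 to 1.15). The same contrast gave 0.15 (-0.17 to 0.48) after normexp correction and 0.05 (-0.43 to 0.69) with the stricter filter. More choroid plexus and meninges in the dissected sample stays open: choroid plexus markers other than Ttr had a median of 0.93, 19 of the 21 with signal in GPHR F/F;Nes had signal in the control too, and with 1 sample per genotype dissection and genotype cannot be told apart for these genes.

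The excess of higher over lower genes in GPHR F/F;Nes was set against 3 explanations. A brightness trend as the whole cause is argued against, since 74.8% of the 2-fold genes were still higher after a loess correction. Leaving out probes with a GA repeat left 5.61 higher genes per lower gene. That outcome was nearly fixed, since 47 of the 1901 higher genes rested on such probes alone. These probes are therefore too few to make the whole excess. The centring of the arrays stays open, because the centre itself sets the balance: 57.1% were higher with each array centred on its median, which put the median of all genes at -0.20, but 68.6% after quantile normalization and 79.1% after normexp correction, which put it at -0.03 and -0.01. No biological explanation was tested. For the genes measured by GA-repeat probes, cross-hybridisation of the repeat is consistent with the other probes of the same genes, whose median was -0.026 against 1.27 for the GA-repeat probes.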

How the results depend on the processing

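Scaling to spike-in RNAs, probes of curated RefSeq mRNAs alone, and leaving out GA-repeat or X and Y probes were chosen after the data were seen. With no replicates, a gene's value was taken as moved when it differed by more than its scanner error. Of 25 lists set apart from random lists, 17 stayed so under every alternative, and 21 under every alternative with random lists matched on level. Median centring, spike-in scaling and the deposited value table shift all genes by 1 constant or nearly so. List percentiles could therefore hardly change under them. The 1901 higher and 328 lower genes became 1077 and 809 with median centring, 1234 and 565 after quantile normalization, 329 and 87 after normexp correction, 5514 and 781 with no filter on dim probes, 498 and 188 with a stricter filter, and 139 and 11000 with spike-in scaling. With RefSeq mRNA probes alone 906 genes were higher. At least 1.5-fold gave 4347 and 1363, and at least 3-fold 548 and 60, by construction. All 328 lower genes and 1077 higher genes were shared between the main setting and median centring, by construction. Gpr89 stood at -0.80 with median centring, -0.79 after quantile normalization, -0.28 after normexp correction and -1.56 with spike-in scaling, and was too dim for a value under the stricter filter. Spike-in scaling moved every difference by -1.03, and turned Aga to -0.0035 and Fas to -0.0021. Median centring moved the median of all genes by -0.28 and quantile normalization by -0.11. Relative to the median of all genes, no list set apart from random lists changed its side after quantile normalization, loess or normexp correction. Under the scalings that shift all genes by 1 constant, no list could change its side.

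Against random lists not matched on level, the percentiles were 89.4 for Golgi structure, 88.7 for COPI and COPII coats, 96.3 for Golgi stress, 90.9 for lysosome, 83.1 for p53 targets and 3.12 for retina and olfactory epithelium. The p53 median was 0.10 after quantile normalization, 0.14 after loess, 0.20 with no filter, 0.072 with the stricter filter and 0.14 without X and Y probes, at percentiles from 95.3 to 96.9. With the stricter filter the microglia median was 0.23 (94.5) and the endothelial one 0.16 (97.2). The retina and olfactory median was -0.12 (3.7) after normexp correction. Of the lists not set apart in the main setting, the cerebellar list was set apart in 8 alternatives, immediate early genes in 4, astrocytes in 3, and the N-glycan, myelin, unfolded protein response and housekeeping lists in 1 each. The cause was not tested for any of these. Of 169 named genes, 155 moved with median centring, 48 after quantile normalization, 17 after loess, 111 after normexp correction and 0 with the deposited value table. Median centring moved every gene by the same -0.28, so its count shows only how many had a smaller scanner error. Signal over background sets which genes are measured, 23946 with the main filter and 13848 with the stricter one.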

Other observations

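The 12 gene lists below were chosen after the data were seen, so their values describe these arrays and test nothing set in advance.

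Genes of neuropeptides and regulated secretion were lower in GPHR F/F;Nes: 25 of 26 lay below 0 and 7 were at least 2-fold lower, with a median of -0.65, below every one of the 10000 random lists. They included Vgf (-2.26), Penk (-2.05) and Tac1 (-1.39). Neuronal genes in general were lower too, with medians of -0.31 for pan-neuronal, -0.45 for GABAergic and -0.29 for glutamatergic genes. Striatal projection neuron genes had a median of -0.41 over 22 genes with 4 at least 2-fold lower, Penk and Tac1 among them, so these lists share members. Cholinergic genes had a median of -0.55 over 9 genes, at the 0.01 percentile, with 3 at least 2-fold lower. They did not all go 1 way: 7 lay below 0 and 2 above, Chat (0.89 ± 0.15) among the latter. The bootstrap interval of this median over genes was -2.40 to 0.16, which includes 0. Genes of the thalamus and habenula had a median of 0.43 over 15 genes, at the 99.2 percentile. Of the hindbrain and spinal cord Hox genes, 3 were measured on both arrays, 2 of them 2-fold higher, and a further 4 had signal in GPHR F/F;Nes alone with bounds of at least 2-fold.

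Collagen synthesis and matrix assembly genes were higher in GPHR F/F;Nes, 12 of 28 at least 2-fold and none 2-fold lower, with a median of 0.83, above every one of the 10000 random lists. Kdelr3 (2.62), Rcn3 (2.51) and Serpinh1 (1.56), which act in the early secretory pathway, belong to this list. Meninges and fibroblast genes moved with it, with a median of 1.31 and 14 of 21 at least 2-fold higher, the collagens Col3a1 (2.62) and Col1a2 (2.61) among them. Of 39 cytosolic ribosomal protein genes, 38 lay above 0, with a median of 0.16 at the 99.7 percentile (84.8 against random lists not matched on level), and none differed 2-fold. Oxidative phosphorylation genes had a median of -0.10 over 39 genes (7.51 percentile, 1.68 not matched on level), cortex and hippocampus projection neuron genes -0.09 over 22 (25.3), hypothalamic genes 0.04 over 14 (8.25), midbrain monoamine neuron genes -0.02 over 11 (8.97) and circadian clock genes -0.05 over 16 (18.7).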
